A study of Mus musculus with 8 samples.

How the data were processed

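RNA had been extracted from bone marrow-derived macrophages on day 7 of differentiation, selected for polyadenylated transcripts, made into libraries with a Kapa mRNA HyperPrep kit and sequenced as read pairs of 150 bases on an Illumina NovaSeq X, per the labels' protocols. Reads were quantified with Salmon 1.4.0 and normalized with DESeq2 against mouse build mm10, per the submitters' processing notes. The annotation release, the import of transcript estimates into genes, any filter and the use of strand are not given in the sources used here. Overlapping and antisense genes and near-identical gene copies are therefore uncertain.

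The deposited values are a signal, not counts: the authors gave 1 normalized value per gene and library, with 34432 rows. In each library every value was a whole number of reads divided by 1 size factor for that library. The division was undone, and 100% of the values came out whole in each of the 8 libraries within a tolerance of 0.01. Size factors lay between 0.901 and 1.04. The recovered reads give 17856715 to 21353207 reads per library, and they were used for depth and for count models as alternatives only. Of the rows, 34415 were matched by gene identifier to a GENCODE annotation of mm10, and 17618 had a read in at least 1 library, of which 15118 were protein-coding genes and 2443 pseudogenes. Symbols are those of the deposited table, and 357 of the rows with reads carry another symbol in the annotation. X-inactivation transcripts were not used here.

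Samples were grouped by the genotype in their titles, 4 libraries per group. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No pair of replicates was a repeat deposit: over the 12 pairs within groups the chi-square per gene was 8.04 to 38.3. The double knockouts fell into 2 pairs, at 8.04 for libraries 1 and 2 and 9.11 for 3 and 4, against 19.3 to 26.5 across the pairs, so these 4 libraries are possibly not independent. Controls also differed in closeness, at 9.32 for libraries 2 and 3 against 38.3 for 1 and 4. Their independence is not known either. No batch or date is given in the labels.

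Genes with a value of at least 10 in at least 4 libraries were tested, 11675 in all. Values were compared as log2(value + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options, two-sided, genotype as the only term). Fold changes are on that scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and 0.05 was the threshold. On the recovered reads, the quasi-likelihood test of edgeR 4.0.16 called 2593 genes higher and 2786 lower, and DESeq2 1.42.0 called 2787 and 2891. Single values such as depth and the targeted genes were compared with exact two-sided permutation tests over the 70 regroupings of 4 against 4, whose smallest p is 0.0286.

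Before the data were examined, 54 gene lists were fixed: pathways, cell type markers, the targeted genes and sex-linked checks. The 49 pathway and marker lists with at least 3 measured members were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with adjustment over the 49 lists. It called 6 lists higher and 5 lower. With an estimated correlation, 3 calls held: mitosis, S phase and replication, and cholesterol synthesis. The fry test, which asks whether a list moves on balance in one direction without comparing it with other genes, called 18 higher and 9 lower. A list's counts adjusted over the list alone used only its own members' p-values.

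Genes named in the text followed a rule that was also fixed before the data were examined. Cdk8 and Cdk19 were always named. The 10 largest rises and the 10 largest falls were taken among genes past the threshold with a mean of at least 50 over all libraries and no overlap between groups, passing over predicted genes, clones and the Y-linked and X-inactivation genes of the sex check. Up to 4 members with the smallest adjusted p were taken from each list described, and a gene with a library far from the rest of its group was added. Some genes that the rule takes, and a test that needs such a gene, are not reported here. Which lists were described with examples was chosen after the list values had been seen, and 4 further lists were added at that stage. Of these, 2 had been put together from genes already seen to rise, so their tests decide nothing and are not reported.

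The pipeline was tested on simulated reads for these 8 libraries, with 200 genes changed among 11675. The limma test recovered 56.7% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.5% of those changed 4-fold, and called 10 of 11450 unchanged genes. The share of changed genes was far below the 46.6% called in the data. Adjusted p-values depend on that share, so these rates do not describe the real comparison. A simulated list of 25 genes raised 1.3-fold was called, and 0 of 50 random lists were. Simulated genes were drawn independently, whereas members of real lists can be correlated (estimated at 0.82 for ribosomal protein genes). The simulation therefore cannot tell how often correlated lists are called wrongly.

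Alternatives chosen before the data were examined were pseudocounts of 0.5 and 8, no filter and a filter of 50, TMM rescaling, quantile normalization, limma without trend and robust options, array weights, the replicate number as a block, each library left out in turn, edgeR and DESeq2 on the recovered reads, camera with an estimated correlation, fry, and tests without X and Y chromosome genes. Tests on protein-coding genes alone, and tests in which the 2 pairs of close double knockout libraries were each averaged, were added after the data had been seen.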

Results

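Polyadenylated RNA was sequenced from mouse bone marrow-derived macrophages, cells grown in culture from marrow precursors, taken without further treatment on day 7 of differentiation. The 8 libraries formed 2 groups of 4. Controls carried a Cre recombinase driven by the Vav promoter, which is active in blood-forming cells. In the double knockout, a floxed Cdk8 gene was the target of the Vav-driven recombinase and Cdk19 was null. Cdk8 and Cdk19 are paralogous kinases of the Mediator complex, which connects transcription factors with RNA polymerase. The comparison asked which transcripts differed in macrophages when both kinases were targeted. Values are normalized read counts, given as mean ± SD with n = 4 per group, and fold changes are double knockout over control.

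Depth was similar in the 2 groups, with 17856715 to 21353207 reads per library (19780843 ± 1312669 in controls and 20786343 ± 492110 in double knockouts, exact permutation p = 0.171, two-sided). Reads fell on 14454 ± 98.5 genes in controls and on 14142 ± 170 genes in double knockouts, without overlap between the groups (exact permutation p = 0.0286, the smallest that 4 against 4 can give). The 10 most abundant genes took 9.54% ± 0.455 of the reads in controls and 10.6% ± 0.461 in double knockouts (exact permutation p = 0.0286). Mitochondrially encoded genes took 3.18% ± 0.314 and 3.51% ± 0.848 (exact permutation p = 0.457). The first principal component held 59.8% of the variance and placed the controls between -47.3 and -39.1 and the double knockouts between 40.3 and 46.2. Within groups the libraries stood apart: the second component (9.41%) held 24.1, 4.42, 1.43 and -25.6 in controls 1 to 4, and -15.7 and -19.0 in double knockouts 1 and 2 against 17.8 and 12.5 in 3 and 4, where mitochondrial reads were 2.60% and 2.98% against 4.27% and 4.19%. Y-linked genes were read in all 8 libraries, with Ddx3y between 1707 and 2278, so the groups did not differ in the presence of a Y chromosome. Ddx3y (log2 -0.28, adjusted p = 0.0146) and Kdm5d (log2 -0.54, adjusted p = 0.0207) were lower in the double knockout, and Eif2s3y and Uty had log2 fold changes of -0.13 and -0.24 (adjusted p = 0.132 and 0.142).

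Cdk19 was strongly reduced in every double knockout library, whereas reads of Cdk8 were largely retained. Cdk19 (ENSMUSG00000038481, chromosome 10, 40339564 to 40483818, mm10) stood at 1452 ± 189 in controls and 372.8 ± 25.8 in double knockouts, leaving 25.7% of the control level. Its log2 fold change was -1.95 (SE 0.10, adjusted p = 2.95e-08, exact permutation p = 0.0286). Single control libraries lay between 1296 and 1682, and double knockout libraries between 342 and 396. Cdk8 (ENSMUSG00000029635, chromosome 5, 146231230 to 146302874, mm10) stood at 438.7 ± 24.5 and 347.3 ± 60.8, so that 79.2% of the control level was left, with a log2 fold change of -0.35 (SE 0.12, adjusted p = 0.0374). Double knockout libraries held 429, 309, 357 and 294, and the first of these lay inside the control range of 408 to 466 (exact permutation p = 0.0571). The call on Cdk8 was lost without control replicates 1, 2 or 4 (adjusted p = 0.0802, 0.0773 and 0.0551) and without double knockout replicates 2, 3 or 4 (0.0965, 0.0563 and 0.104). It was also lost without a filter on low values (0.0550), without the trend and robust options (0.0501), under quantile normalization (0.0867) and with double knockouts 1 and 2 averaged and 3 and 4 averaged (0.0519). Gene totals include exons outside the floxed part, so the Cdk8 total does not check whether the kinase was removed, and the kind of Cdk19 null allele is not given in the sources used here.

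**Figure D1:**
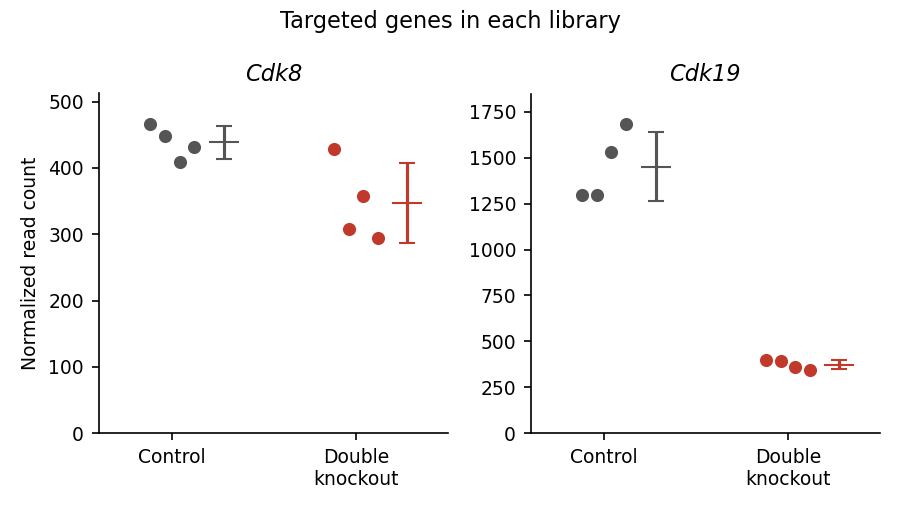
Normalized read counts of Cdk8 and Cdk19 (vertical axes, from 0) in each of the 4 control and 4 double knockout libraries (points), with the group mean and SD beside them. Cdk19 lies at 342 to 396 in the double knockouts against 1296 to 1682 in controls, while the Cdk8 values of the groups overlap.

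Few of the remaining Mediator genes changed. Of the other subunits of the Mediator kinase module, Med13l fell (log2 -0.42, SE 0.12, adjusted p = 0.0132, and 0.0566 with the double knockout pairs averaged) and the other 4 measured members did not pass the test, with the same counts adjusted over the list alone. Ccnc, the cyclin partner of both kinases, stood at 592.9 ± 55.9 and 678.2 ± 88.2 (adjusted p = 0.185), and Med12 at 677.1 ± 178 and 943.4 ± 389 (adjusted p = 0.299, and 0.0299 without double knockout replicate 2). Of 26 core Mediator subunits, 6 rose and 2 fell, also when adjusted over the list alone. Med14, a scaffold subunit, fell from 849.3 ± 166 to 388.4 ± 50, and Med28 rose from 1049 ± 54.7 to 1687 ± 190. Neither list passed with camera (adjusted p = 0.986 and 0.570), while the core subunits were higher on balance (fry adjusted p = 0.0215).

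Expression differed widely between the genotypes. Of 11675 genes tested, 2671 were higher and 2773 lower in the double knockout (limma, Benjamini-Hochberg adjusted p under 0.05), together 46.6% of the tested genes. Changes of at least 2-fold were found for 430 higher and 841 lower genes. The groups did not overlap for 5011 genes, 42.9% of those tested, where chance gives 2.86% for 4 against 4. The median log2 fold change of all tested genes was 0.01, a value that the normalization of the libraries largely sets. Of 49 gene lists tested with camera, 6 were called higher and 5 lower, while other splits of the same libraries called up to 7 lists in a direction. Splits that exchange a single library of each genotype keep part of the genotype difference. Splits with equal numbers of both genotypes on each side keep none of it, and they still called up to 5 lists in a direction. The number of lists called is therefore not evidence of a genotype effect.

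Among genes that the naming rule admits, with a mean of at least 50 and no overlap between groups, the largest rises were those of Klra3, Ctse, Epb41l3 and Rhou. Ctse, which encodes the aspartic protease cathepsin E, rose 20.3-fold, from 68.96 ± 5.20 to 1418 ± 94.6 (adjusted p = 1.89e-10). Rhou rose 17.3-fold from 18.88 ± 11 to 306.6 ± 23.5. Klra3, an inhibitory lectin-like receptor known from natural killer cells, rose from 10.57 ± 7.64 to 233.3 ± 6.29. Its value is uncertain because it belongs to a family of closely related genes among which reads can be divided. Mmp13, a collagenase, rose 13.4-fold from 252.8 ± 34.3 to 3391 ± 229, and Cela1, an elastase, 14.7-fold to 2359 ± 291. Rises of 12.7- to 18.9-fold were also found for Epb41l3, Slc22a23, Lrmda, Ms4a4a and Adcy3.

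Large falls included those of monocyte and cell division genes. Sgo2a, a protector of centromeric cohesion, fell 35.1-fold from 456.4 ± 53.3 to 12.09 ± 2.00 (adjusted p = 1.88e-09). Cd207, which encodes the lectin langerin, fell 24.4-fold to 5.665 ± 3.90, and Smpdl3b, a sphingomyelin phosphodiesterase-like enzyme, fell 18.2-fold to 33.8 ± 8.19. Ccr2, the receptor for the monocyte chemoattractant Ccl2, fell 15.6-fold from 1294 ± 21.7 to 83.57 ± 19.4. Rrm2, the regulated subunit of ribonucleotide reductase, fell 14.2-fold from 3360 ± 158 to 237.3 ± 32.6. Stxbp6, Aunip, Depdc1a and Radx fell between 14.8- and 16.8-fold.

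**Figure D2:**
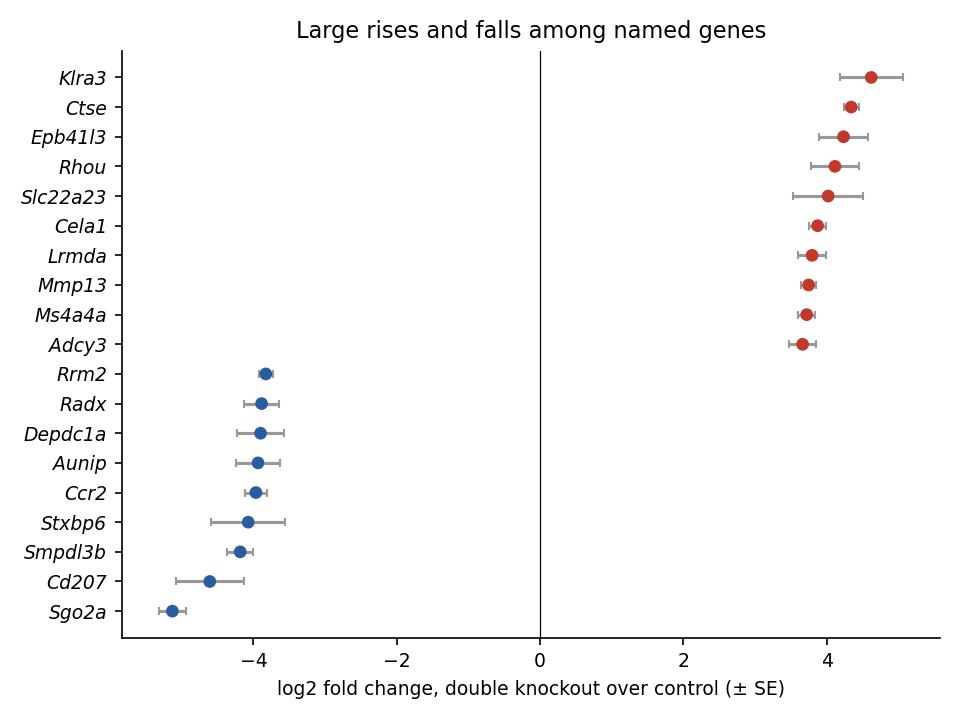
Log2 fold change, double knockout over control, with its standard error (horizontal axis) for 10 named genes with large rises and 9 with large falls. Rises reach 4.62 for Klra3 and the falls shown reach -5.13 for Sgo2a.

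Genes of the cell cycle fell throughout. All 30 measured mitosis genes fell, with a median log2 fold change of -3.01 (camera adjusted p = 5.22e-26, and adjusted p = 0.00265 with an estimated correlation), and the count was also 30 adjusted over the list alone. Mki67, the proliferation marker Ki-67, fell 10.8-fold from 3838 ± 370 to 354.5 ± 28.7, Top2a, a topoisomerase of chromosome segregation, 8.40-fold from 5426 ± 94.4 to 652 ± 110, and Ccnb1, the mitotic cyclin B1, 8.004-fold. Cdk1, the kinase that drives mitotic entry, fell 4.18-fold from 2213 ± 183 to 528.1 ± 16.3. All 30 S phase and replication genes fell as well, also adjusted over the list alone, with a median of -1.83 (camera adjusted p = 5.33e-24, and adjusted p = 0.00872 with an estimated correlation). Among them Uhrf1, which maintains DNA methylation, fell 7.08-fold, Tk1, a thymidine kinase, 7.49-fold, and Mcm5, a subunit of the replicative helicase, 4.70-fold. Ccnd1, which encodes cyclin D1, fell 4.01-fold from 26444 ± 1283 to 6593 ± 220, and Myc 2.28-fold from 758.1 ± 68.5 to 335.4 ± 59.7. Monocyte and neutrophil markers moved in the same direction, with medians of -1.60 and -1.35.

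More p53 targets fell than rose. Of 21 measured, 3 rose and 10 fell, also adjusted over the list alone. The list was lower on balance (fry adjusted p = 2.33e-06), but its difference from other genes did not pass the test (camera adjusted p = 0.105). Cdkn1a, the cell cycle inhibitor p21, fell 1.78-fold to 6016 ± 276, and Mdm2, which encodes the ubiquitin ligase of p53, fell 1.61-fold. Gtse1, a G2 and S phase protein, fell 4.19-fold, and Gadd45a, a growth arrest gene, rose 4.27-fold to 952.8 ± 141. Of 5 measured Wnt targets, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.428, and fry adjusted p = 2.90e-06, lower). Ccnd1 and Myc fell, Fzd7 rose 2.21-fold, and Znrf3 stood at 154.9 ± 18.5 and 134.9 ± 18.2.

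Cholesterol synthesis genes rose together. Of 24 measured, 21 rose and none fell, also adjusted over the list alone, with a median log2 fold change of 0.70 (camera adjusted p = 8.53e-09, and adjusted p = 0.00872 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, rose 2.56-fold from 734.5 ± 54.3 to 1880 ± 87.7, Hmgcs1, the cytosolic HMG-CoA synthase, 2.40-fold, and Cyp51, a sterol demethylase, 1.99-fold. Fatty acid synthesis genes moved both ways, with 3 higher and 5 lower of 16, also adjusted over the list alone (camera adjusted p = 0.986). In that list Scd2, a stearoyl-CoA desaturase, rose 6.07-fold from 94.58 ± 10.4 to 579.4 ± 65.8, and Fads2, a desaturase of polyunsaturated fatty acids, fell 2.21-fold. Monocyte and neutrophil markers were lower in the same libraries, with medians of -1.60 and -1.35.

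Genes of lipid uptake and storage were mostly higher. Of 17 measured, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with camera adjusted p = 0.0129 and adjusted p = 0.166 with an estimated correlation. Fabp5, a fatty acid carrier, rose 8.44-fold from 1855 ± 138 to 15629 ± 501. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 2.63-fold to 81796 ± 5787, and the scavenger receptor gene Cd36 2.17-fold to 53357 ± 4311. Of 19 LXR targets and cholesterol efflux genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone). The list did not pass with camera (adjusted p = 0.0567), but was higher on balance (fry adjusted p = 0.00117). Abcg1, a sterol exporter, rose 3.002-fold and Mylip, a ubiquitin ligase, 2.26-fold. Ch25h, the cholesterol 25-hydroxylase, fell 7.08-fold from 2017 ± 239 to 282.9 ± 15.7. The falls of monocyte and neutrophil markers (medians -1.60 and -1.35) were in the same libraries.

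Lysosomal genes were higher in the same libraries in which monocyte and neutrophil markers were lower. Of 39 measured, 25 rose and 3 fell (26 and 3 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 5.37e-07, and adjusted p = 0.307 with an estimated correlation). The protease gene Ctsl rose 3.26-fold from 36779 ± 2177 to 119913 ± 4382, Cd63, a tetraspanin of late endosomes, 2.60-fold, Ctsz 2.36-fold, and Lgmn, the asparaginyl endopeptidase, 2.17-fold. Iron handling genes included 9 that rose and 1 that fell of 19, also adjusted over the list alone (camera adjusted p = 0.00220, and adjusted p = 0.0915 with an estimated correlation). Slc40a1, the iron exporter ferroportin, rose 4.21-fold from 916.5 ± 36.8 to 3859 ± 106. Steap3, a ferrireductase, rose 3.45-fold, and Spic, a transcription factor of iron-recycling macrophages, 6.89-fold from 41.48 ± 3.35 to 293.7 ± 47.4. Of 21 NRF2 antioxidant genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0264 and adjusted p = 0.710 with an estimated correlation. That call was also lost under quantile normalization (adjusted p = 0.1004) and without the trend and robust options (adjusted p = 0.0511). Hmox1, the haem-degrading oxygenase, rose 1.58-fold to 41792 ± 3597, and Gclm, a subunit of the glutathione synthesis enzyme, 1.51-fold. Of 44 ribosomal protein genes, 21 rose and none fell (22 and none adjusted over the list alone), by at most 0.52 on the log2 scale for named members Rpl30, Rps14, Rpl23 and Rplp1. Their set test gave camera adjusted p = 0.00106, and adjusted p = 0.980 with an estimated correlation. These genes also differed within groups: Rplp1 stood at 21980, 19842, 18527 and 16322 in controls 1 to 4, and at 23567 and 23900 in double knockouts 1 and 2 against 32517 and 30859 in 3 and 4.

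**Figure D3:**
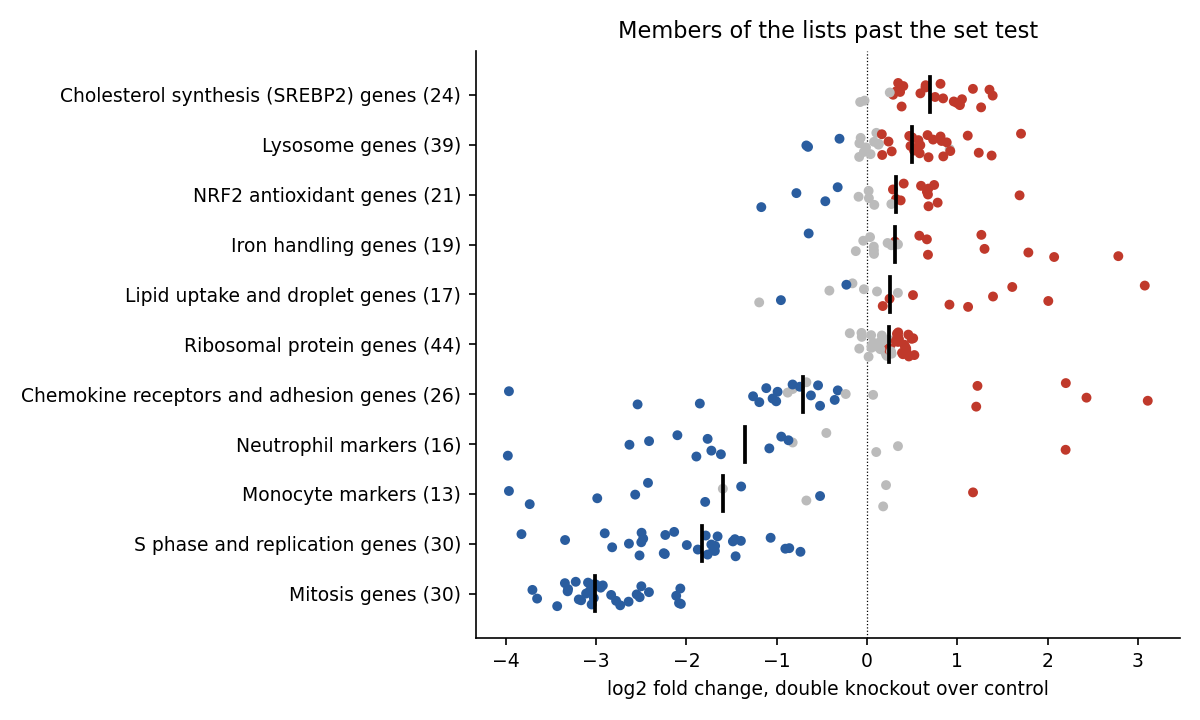
Log2 fold change, double knockout over control (horizontal axis), of each measured member (points) of the 11 lists past the set test, with the list median as a black bar and the number of measured members in brackets. Red members rose, blue members fell and grey members did not pass the test; mitosis genes lie around their median of -3.01 and cholesterol synthesis genes around 0.70.

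Macrophage markers shifted both ways. Of 20 macrophage markers, 12 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0820, and fry adjusted p = 0.00110, higher). Lamp1, a lysosomal membrane protein, rose 1.60-fold to 37199.6 ± 1286, and Mertk, a receptor for apoptotic cells, 2.11-fold to 2019 ± 245. Csf1r, the receptor for macrophage colony-stimulating factor, fell 1.75-fold from 44395 ± 3620 to 25388 ± 1349, and Lyz2, a lysozyme gene, 1.66-fold. Among 23 macrophage lineage transcription factors, 7 rose and 6 fell (8 and 6 adjusted over the list alone). The list did not pass with camera (adjusted p = 0.763), but was higher on balance (fry adjusted p = 0.00217). Cebpa, a regulator of myeloid differentiation, rose 2.50-fold from 2998 ± 223 to 7513 ± 650, Bhlhe40 rose 2.52-fold, and Klf4 fell 3.19-fold.

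Monocyte and neutrophil markers were lower. Of 13 monocyte markers, 8 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00494, and adjusted p = 0.213 with an estimated correlation). Beside Ccr2, F13a1, a coagulation factor subunit, fell 13.3-fold from 326.7 ± 73.8 to 23.93 ± 7.37, and Chil3, a chitinase-like protein, 5.93-fold, whereas Nr4a1, a nuclear receptor of patrolling monocytes, rose 2.26-fold. Of 16 neutrophil markers, 11 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.710 with an estimated correlation). S100a9, a calcium-binding protein of myeloid cells, fell 5.33-fold from 759 ± 172 to 139.9 ± 17.7, and Ltf, which encodes lactoferrin of neutrophil granules, 6.20-fold. Without control replicate 1 the neutrophil list gave adjusted p = 0.0555. Of 7 haematopoietic progenitor markers, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.622, and fry adjusted p = 5.43e-06, higher). Cd34 fell 4.72-fold from 1134 ± 41.5 to 242.3 ± 41.6, while Sox4 rose 6.54-fold from 222.4 ± 13.99 to 1461 ± 99.5.

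Chemokine receptor and adhesion genes were mostly lower. Of 26 measured, 16 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 0.00400, and adjusted p = 0.307 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell 5.82-fold from 12955 ± 386 to 2237 ± 285. Against this direction Cxcr4, the receptor for Cxcl12, rose 4.60-fold from 1332 ± 33.2 to 6140 ± 325, and Ccr3, the eotaxin receptor, 8.63-fold from 281.9 ± 36.5 to 2428 ± 121. Monocyte markers, which share Ccr2 with this list, were lower in the same libraries.

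Markers of lymphocytes and eosinophils were few. Of 5 measured T and NK cell markers, 3 rose and none fell (camera adjusted p = 0.0567), of 3 B cell markers 1 rose and 2 fell (camera adjusted p = 0.986), and of 3 eosinophil markers 2 rose and none fell (camera adjusted p = 0.105). These counts were the same adjusted over the list alone. The T and NK cell list and the eosinophil list were higher on balance (fry adjusted p = 0.000165 and 1.41e-05). Cd4 rose 5.78-fold from 23.91 ± 9.26 to 136 ± 17.7, Ccl5, a chemokine gene also used by macrophages, 3.01-fold, and Il7r 1.62-fold, while Lck stood at 8.86 ± 7.03 and 8.671 ± 5.89. Ighm, the immunoglobulin mu chain gene, fell from 133.2 ± 21.1 to 89.3 ± 27.2 (adjusted p = 0.0364), a call that edgeR did not make (adjusted p = 0.0519) and that was lost with the double knockout pairs averaged (adjusted p = 0.0656). Prg2, an eosinophil granule gene, rose 8.34-fold from 2.12 ± 2.42 to 21.86 ± 11.7 (adjusted p = 0.00320), and Siglecf stood at 14.3 ± 4.68 and 12.59 ± 3.85. Blnk, an adaptor of B cell receptor signalling, rose 1.52-fold and Cd79b fell 2.60-fold. Of 9 osteoclast markers, 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.651, and fry adjusted p = 0.00200, higher). Itgb3, the integrin beta 3 subunit, rose 10.5-fold from 38.16 ± 7.65 to 405.7 ± 42.8. Dendritic cell markers had 2 higher and none lower of 5, megakaryocyte markers 1 and none of 3, stromal markers none and 3 of 6, endothelial markers 1 and 1 of 4 (1 and 2 adjusted over the list alone) and adipocyte markers 2 and 2 of 4. None of these 5 lists passed with camera (adjusted p between 0.192 and 0.986). On balance the megakaryocyte and adipocyte lists were higher (fry adjusted p = 0.00217 and 0.0138) and the stromal list lower (fry adjusted p = 0.0165). No mast cell or erythroid marker passed the filter on low values.

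**Figure D4:**
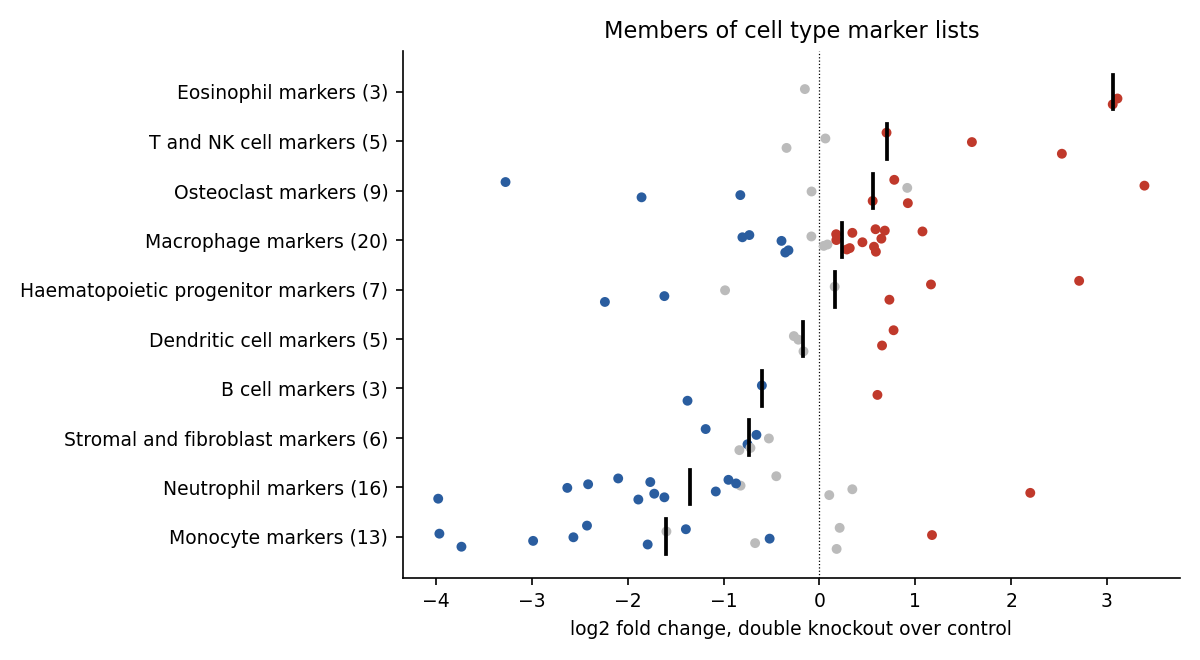
Log2 fold change, double knockout over control (horizontal axis), of each measured member (points) of 10 cell type marker lists, with the list median as a black bar and the number of measured members in brackets. Red members rose, blue members fell and grey members did not pass the test; the monocyte and neutrophil medians are -1.60 and -1.35.

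Genes for clearing dead cells and remodelling matrix changed in both directions. Of 23 phagocytosis and efferocytosis genes, 9 rose and 10 fell (9 and 11 adjusted over the list alone). The list did not pass with camera (adjusted p = 0.790), but was higher on balance (fry adjusted p = 0.000251). Gas6 and Pros1, the ligands that bridge dying cells to Mertk and its relatives, moved apart: Gas6 rose 4.39-fold from 5994 ± 375 to 26323 ± 1301 and Pros1 fell 9.48-fold from 1068 ± 133 to 111.4 ± 10.4. Mfge8, another bridging protein, rose 4.54-fold, and Fcgr2b, the inhibitory Fc receptor, 5.44-fold. Of 26 matrix and matrix protease genes, 11 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.653, and fry adjusted p = 0.000110, higher). Beside Mmp13, the macrophage elastase gene Mmp12 rose 4.88-fold and Timp2, a protease inhibitor, 4.14-fold, while Plau, the urokinase gene, fell 3.18-fold. Of 16 complement genes, 7 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.986), with C1qa 1.57-fold higher and the anaphylatoxin receptor gene C5ar1 1.57-fold lower.

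Inflammatory and interferon genes showed no common direction. Of 41 type I interferon-stimulated genes, 14 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.300), with Rsad2, an antiviral enzyme, 1.85-fold higher. Of 29 interferon-gamma and antigen presentation genes, 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.986), and Cxcl10 fell 4.55-fold from 567.4 ± 92.9 to 125.8 ± 32.0. Of 25 NF-kB and cytokine genes, 6 rose and 9 fell (6 and 11 adjusted over the list alone), with camera adjusted p = 0.651. Icam1, an adhesion receptor, fell 3.61-fold and the chemokine gene Ccl7 rose 3.67-fold. Of 14 alternative activation genes, 4 rose and 4 fell (camera adjusted p = 0.986), and of 17 IL-10 axis genes, 5 rose and 4 fell (camera adjusted p = 0.763), both also adjusted over the list alone. Clec7a, the beta-glucan receptor dectin-1, rose 2.81-fold, and Tgfbi, a matrix protein induced by TGF-beta, fell 2.02-fold.

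The metabolic and stress lists not described above did not pass with camera. Oxidative phosphorylation genes included 12 that rose and 3 that fell of 36 (11 and 2 adjusted over the list alone), with camera adjusted p = 0.105. Glycolysis genes had 3 higher and 4 lower of 19, and fatty acid oxidation genes 5 higher and 5 lower of 19 (5 and 6 adjusted over the list alone). Hypoxia response genes had 7 higher and 5 lower of 19, and unfolded protein and integrated stress response genes 8 higher and 9 lower of 25. Heat shock genes had 3 higher and 4 lower of 14, and none of the 13 mitochondrially encoded genes passed the limma test, also at an unadjusted p under 0.05, nor did any with edgeR or DESeq2. Immediate early genes had 8 higher and 9 lower of 24 (8 and 10 adjusted over the list alone), Toll-like and pattern recognition genes 8 and 7 of 28, and TGF-beta targets 5 and 7 of 23. Of 15 other transcription-elongation kinases and cyclins, 2 rose and 2 fell (1 and 2 adjusted over the list alone), and of 6 Notch targets 1 rose and 2 fell. Where no second pair of counts is given, the counts were the same adjusted over the list alone. Their camera adjusted p-values lay between 0.105 and 0.986. On balance the hypoxia list was higher and the heat shock list lower (fry adjusted p = 0.000125 and 0.0375).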

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

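The tests of scaling, progenitors, monocytes, retained exons, intact alleles, T cells and eosinophils were chosen only after the results had been seen. In 12 of 280 groups checked (4.29%), 1 library lay far from the other 3 by the ratio of its gap to the group's range, and chance gives about 1 in 20. In controls this held for Cyp51 (ratio 0.948, replicate 1 at 841 against 746 to 751), Fabp5 (0.837, replicate 4 low), Lck (0.836, replicate 4 high), Ccl7 (0.887, replicate 1 high) and Med14 (0.929, replicate 4 at 1098 against 758 to 782). In double knockouts it held for Mdm2 (0.939, replicate 2 low), Cyp51 (0.872, replicate 1 low), S100a9 (0.846, replicate 1 low), Blnk (0.8293, replicate 1 low), Ighm (0.953, replicate 3 at 130.0 against 74.1 to 76.7), H2-DMa (0.893, replicate 1 high) and Med13 (0.848, replicate 2 high). Leaving out single libraries changed the call on Ighm (adjusted p = 0.0364 with all libraries), which was lost without control replicates 2 (0.101) and 3 (0.0853) and double knockout replicates 1 (0.0845), 2 (0.0850) and 4 (0.0894). Med13 (log2 -0.25, adjusted p = 0.0869) passed without control replicate 2 (adjusted p = 0.0415), and Med12 (log2 0.41, adjusted p = 0.299) without double knockout replicate 2 (adjusted p = 0.0299).

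Regrouping the 8 libraries into 4 against 4 gives 35 splits. The real split was the 1 split with as many genes higher (2671) and lower (2773). The same held for those changed at least 2-fold (430 and 841), and the highest of the others was 1 gene. All other splits mix the genotypes, which widens the spread within their groups and lowers their counts. A share of 1 in 35 is also the smallest possible. It takes the libraries as independent, which the close double knockout pairs leave in doubt, so chance is not excluded by this test. For the number of lists called, 6 splits gave as many as the 6 lists higher and 16 as many as the 5 lists lower. The highest of the others was 7. Splits that exchange a single library of each genotype keep part of the genotype difference. Splits with equal numbers of both genotypes on each side keep none of it. Of these, 1 called 5 lists in a direction and 1 in the other, another called 0 and 4, and some called none. Camera at the preset correlation thus called lists without a genotype difference between the sides. The counts of lists therefore do not show that the list calls come from the genotype.

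Cell cycle genes fell in the double knockout. Scaling of a library shifts all its genes alike. The mitosis median was -3.01 against 0.01 for all tested genes, which argues against scaling for the fall relative to other genes. The mitosis median was still -2.92 under quantile normalization, but that setting moved the median of all genes only to 0.05, so it adds little. The 7 measured markers of haematopoietic progenitors did not fall together, with a median of 0.16 (SD 1.73 between markers). They ran from -2.24 for Cd34 to 2.71, and 3 rose and 2 fell. The list was higher on balance (fry adjusted p = 5.43e-06), but did not pass with camera (adjusted p = 0.622). Markers that run both ways cannot tell whether progenitors were lost, so that explanation stays open. Fewer monocytes cannot be told apart from a change within the macrophages, because the median of the monocyte markers, -1.60, lies within their own spread of the mitosis median (SD 1.58). An effect of the genotype on division of the cultured cells stays open and was not tested.

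Reads of Cdk8 were left at 79.2% of the control level in the double knockout. Reads shared with the paralog Cdk19 are argued against, since 0% of the 9816 words of 31 bases in Cdk8 transcripts also occur in Cdk19 transcripts. Transcripts that keep exons outside the removed part and cells that kept an intact allele cannot be told apart with totals per gene: either could leave the 79.2%, and counts per exon were not used here.

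Some genes known from lymphocytes or eosinophils rose and others did not. Cd4 and Ccr3 rose, as did Cd28 (adjusted p = 4.08e-09), Lag3 (adjusted p = 5.63e-06) and the B cell gene Cd22 (169 reads in controls and 1302 in double knockouts, adjusted p = 2.06e-05), which were picked after their values were seen. Against this, Cd8a had 123 reads in controls and 121 in double knockouts, Siglecf 57 and 51, and Cd79b fell. Neither the T and NK cell list nor the eosinophil list passed with camera (adjusted p = 0.0567 and 0.105). Both were higher on balance (fry adjusted p = 0.000165 and 1.41e-05). T cells are argued against as the source of the Cd4 reads, since Cd3d, Cd3e, Cd3g, Thy1 and Cd2 together had 1 read in the double knockouts, 0.182% of the 550 reads of Cd4. Eosinophils are argued against as the source of most Ccr3 reads, since Epx, Prg2 and Prg3 together reached 0.895% of the 9832 reads of Ccr3, although Prg2 itself rose from 8 to 88 reads, and no biological explanation was tested.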

How the results depend on the processing

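The tests on protein-coding genes alone and with the 2 pairs of close double knockout libraries averaged were chosen after the data had been seen. Counts of genes higher stayed between 1924 and 3038 and of genes lower between 2208 and 2915 over all alternatives, within 1.5 times those reported, and no gene was called in opposite directions. Quantile normalization moved the median of all genes most, to 0.05, with 54.8% of calls higher against 49.1%. Leaving out single libraries gave 2244 to 2614 genes higher, 2353 to 2681 lower, 360 to 446 higher and 746 to 846 lower by at least 2-fold, 6 to 9 lists higher and 4 to 5 lower. Cdk19 stayed past the threshold throughout, at log2 -2.00 to -1.88 without single libraries. Cdk8 kept its direction but missed the threshold in 11 of 22 alternatives: at -0.35 without a filter (adjusted p = 0.0550), without trend and robust options (0.0501) and with the replicate block (0.0517), at -0.27 under quantile normalization (0.0867), at -0.34 with the double knockout pairs averaged (0.0519), and in 6 of 8 fits without 1 library, which ranged from -0.46 to -0.28 (adjusted p 0.00779 to 0.104). The cause was not tested. No sign was found that the replicate numbers pair the samples: deviations of same-numbered libraries correlated at -0.05 to 0.03, and 0 of 4 numbers matched best with their own. This does not show that same-numbered samples were handled apart. With the replicate block, 2215 genes were higher and 2434 lower. With the double knockout pairs averaged, 1924 genes were higher and 2208 lower, 389 and 801 by at least 2-fold, with 7 lists higher and 5 lower, and the calls on Ighm (adjusted p = 0.0656) and Med13l (0.0566) were lost. Lists called higher and lower numbered 10 and 6 with DESeq2, 1 and 2 by camera with an estimated correlation, and 18 and 9 by fry. The calls on NRF2 genes were lost under quantile normalization (adjusted p = 0.1004) and without trend and robust options (0.0511), and that on neutrophil markers without control replicate 1 (0.0555). Under quantile normalization B2m turned from 0.30 to -0.033 (adjusted p = 0.604). Of 134 other named genes, 129 kept their direction and side of the threshold throughout, and B2m, Ighm, Med12, Med13 and Med13l did not. At this depth and with 4 libraries per group, simulated 1.5-fold changes were recovered in 56.7% of genes. That simulation changed 200 of 11675 genes, whereas 46.6% were called in the data, and adjusted p-values depend on that share. The 56.7% is therefore not the sensitivity of this comparison. Whether depth or the spread between libraries sets it was not tested.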

Other observations

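The 2 lists in this part were put together after other list values had been seen. Subunits of the V-ATPase, the pump that acidifies lysosomes, rose in 13 of 16 cases, with a median log2 fold change of 0.35 (camera p = 3.21e-05, and p = 0.0204 with an estimated correlation). Of these 16 genes, 2 (Atp6v0d1 and Atp6v1h) also belong to the lysosome list. Atp6v1g1 rose from 3456 ± 401 to 6256 ± 669 and Atp6v0b from 3968 ± 362 to 6022 ± 317. Fanconi and homologous recombination genes fell in 18 of 24 cases and rose in none, with a median of -2.21 (camera p = 6.16e-10, and p = 0.00223 with an estimated correlation). Brca1 fell from 898.7 ± 129 to 152.2 ± 9.93, while Brca2 stood at 251.5 ± 84.8 and 183.2 ± 72.2 (adjusted p = 0.304).

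A pair of pseudogenes, Gm28438 and Gm46223, lies outside the rule for named genes and was chosen after the values had been seen. Gm28438 stood at 263.4 ± 206 in controls and was at 0 in all 4 double knockout libraries, and Gm46223 fell from 3610 ± 97.3 to 391.7 ± 19.7 (adjusted p = 6.87e-11). Both can share reads with related genes, so their values are uncertain.

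Alleles carried along with the targeted genes would raise the share of called genes near Cdk8 and Cdk19. Within 5 Mb of either gene, 49 of 104 tested genes were called (47.1%), against 46.6% elsewhere (one-sided Fisher exact p = 0.499, odds ratio 1.02, 95% interval 0.678 to 1.53). The share was 42.4% near Cdk8 (28 of 66 genes) and 55.3% near Cdk19 (21 of 38), and the 2 flanks were not tested apart. Changes of at least 2-fold were fewer near them, 4 of 104 genes (3.85%) against 10.9% elsewhere (two-sided Fisher exact p = 0.0167), which runs against a raised share of large changes. The interval is too wide to tell whether some of the 104 genes differ for that reason.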
